A study of Rattus norvegicus with 28 samples.

How the data were processed

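Messenger RNA was measured in 28 libraries in 8 groups. Cells came from the cortex of Wistar rats at postnatal day 1 and grew for 10 days in flasks, from which microglia were shaken off and sorted with CD11b/c magnetic beads. Per the labels, microglia were stimulated 1 day and astrocytes 3 days after isolation, in medium with 10% FCS, with ENV (1 µg/ml, vehicle buffer) or LPS (100 ng/ml, vehicle H2O). Libraries were made by mRNA capture (VAHTS Universal V6) from 150 ng total RNA. Each group had 3 libraries in microglia and 4 in astrocytes, numbered by replicate in the sample titles. Whether replicates came from separate litters, and whether ENV and LPS sets shared animals, is not given in the sources used here. The p-values therefore measure the spread between these libraries, which may be technical.

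The deposited files hold counts: whole numbers per gene symbol for each library, not normalized. HISAT2, StringTie 1.3.3b and the assembly mRatBN7.2 are named in the submitters' processing notes. The roles and settings of these tools, the annotation release and the strand of the libraries are not given in the sources used here. Totals were 26513999 to 42724111 counts per microglial library and 23742228 to 35326938 per astrocyte library, and a count of 0 allowed up to 3 counts, or 0.0702 to 0.126 CPM per library. Reads were not marked by molecular identifiers, so intervals and floors cover counting error only. The microglial tables listed 23139 genes (5345 at 0 in every library, 411 with a numbered copy of a symbol), and for astrocytes 20268 genes were listed in the ENV set and 20056 in the LPS set. Symbols shared with the microglial tables numbered 15344 and 15246, and genes were joined by symbol alone. Of the listed genes, 16648, 16854 and 16696 matched a current rat gene symbol in the supplied reference table and 1485, 178 and 174 a synonym; that table follows a later assembly and was used for names alone. Reads shared between paralogs (RT1, Ifit, Oas, Ccl, Cxcl, Klra, Lilrb and Olr families and numbered copies) or between overlapping genes could not be separated.

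Each treated group was compared with its own vehicle within its cell type by the edgeR quasi-likelihood F test, 2-sided (TMM normalization, filterByExpr, robust fit; edgeR 4.0.16, limma 3.58.1, R 4.3.3). Adjusted p-values are those of edgeR after Benjamini-Hochberg adjustment over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. Log2 changes are given with their standard error, CPM with the standard deviation. The ENV response minus the LPS response in each cell type, and each response in microglia minus that in astrocytes, were tested as interaction terms, the latter over symbols in both gene tables. Vehicles were compared with each other within each cell type. A direction is relative to the median gene under the normalization used. Median changes of all genes lay between -0.06 and 0.08 except in the LPS difference between cell types (-0.12).

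The 34 gene lists, 25 of functions and 9 of cell type markers, were written before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives, apart from alternatives that used replicates 1 and 2 or 3 and 4 alone or a block shared by both sets. Some tests of explanations were also written after results were seen, and each is named as such where it is given. Lists were tested with camera (limma) with a preset correlation between genes of 0.01, adjusted over the lists with at least 3 tested members. An estimated correlation, the self-contained test fry, a replicate block and DESeq2 size factors were alternatives. Members past the threshold were counted with the adjustment over all genes and with the adjustment over the list alone. Some genes are members of more than 1 list. The functional lists covered NF-kB targets and feedback, the TLR4 receptor complex and adaptors, cytokines, chemokines, interferon-stimulated genes, MHC class I, MHC class II and co-stimulation, nitric oxide with prostaglandin and oxidative burst, NRF2 antioxidant genes, complement, homeostatic and disease-associated microglia, alternatively activated macrophages, pan-reactive, A1, A2 and homeostatic astrocytes, cholesterol synthesis, cell cycle, glycolysis, oxidative phosphorylation, extracellular matrix and proteases, lysosome and phagocytosis, growth and neurotrophic factors, and immediate early and stress genes. Marker lists covered microglia and macrophages, astrocytes, the oligodendrocyte lineage, neurons, endothelium, fibroblasts and mural cells, ependymal cells and choroid plexus, granulocytes and blood monocytes, and lymphocytes.

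Named genes followed a rule. In each treated comparison they were the 6 largest rises and 6 largest falls among called genes whose groups did not overlap in log2 CPM (prior count 2), with a mean of at least 10 CPM in the higher group and an assigned symbol. To these were added a panel of 20 genes given whatever their result, and up to 4 members of each list with the smallest adjusted p. For differences between responses the rule took 5 genes per direction and the panel. Serpina3n of the panel was not analysed here, nor were Arg1 in astrocytes, Slc1a2 in LPS-treated microglia and Il10 in LPS-treated astrocytes, which did not pass the filter. Where every vehicle library had no counts, the fold is a lower bound against a floor of 3 counts per library on average; with 1 to 3 counts over the group the ratio is given with its 95% counting interval.

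Replicate numbers were checked as a pairing by correlating residual log2 CPM of treated and vehicle libraries of the same number across genes. These correlations were 0.317, 0.469 and 0.432 for microglial ENV, 0.423, 0.416 and 0.514 for microglial LPS, 0.510, 0.638, 0.260 and 0.566 for astrocyte ENV and 0.607, 0.529, 0.549 and 0.634 for astrocyte LPS. Buffer and H2O astrocyte libraries of equal number correlated at 0.276, 0.559, 0.480 and 0.770. Comparisons were fitted without a block, and the replicate number was used as a block in an alternative.

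Other alternatives were DESeq2 size factors in the same edgeR fit, no filter on low counts, the DESeq2 Wald test (1.42.0), a joint fit of the 4 groups of a cell type, an absolute log2 change of at least 1, and leaving out each library in turn. Every other split of the libraries into groups of equal size was fitted as well, or for interactions 60 relabelled splits. The whole procedure was tested on simulated data, in which counts with the observed dispersions received known changes. In each, 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold, beside 1 spiked list. Fewer genes changed than were called in the treated comparisons, so the adjusted threshold was stricter in the simulation. Recovered shares and shares of wrong calls hold for that setting. The share of wrong calls among those made there was 11.2% for microglial ENV, 10.6% for microglial LPS, 4.55% for astrocyte ENV and 7.69% for astrocyte LPS. A spiked list of 25 members with 2-fold changes was found in all 4 comparisons, with 1 other list called in microglial LPS. Genes were drawn independently there, so the simulation cannot show how the list test behaves when genes correlate. Other splits of the real libraries called up to 17, 16, 18 and 16 lists (microglial ENV and LPS, astrocyte ENV and LPS).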

Results

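Primary rat microglia and astrocytes were profiled after stimulation with the envelope protein of the human endogenous retrovirus W (ENV), a retroviral surface protein, or with lipopolysaccharide (LPS), a bacterial wall component sensed by TLR4. ENV at 1 µg/ml was set against its buffer and LPS at 100 ng/ml against water (H2O), with 3 libraries per group in microglia and 4 in astrocytes. Library totals ran from 26513999 to 42724111 counts in microglia and from 23742228 to 35326938 in astrocytes. A count of 0 therefore allowed up to 0.0702 to 0.126 CPM (counts scaled to a library total of 1e+06) in a library. The duration of stimulation is not given in the sources used here.

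Each culture carried its own cell type's transcripts at high level and the other type's at low level. Summed markers of microglia and macrophages, such as the calcium-binding protein gene Aif1 and the integrin gene Itgam, reached 12892 ± 1825 CPM (SD, n = 3) in buffer-treated microglia and 538 ± 328 CPM (n = 4) in buffer-treated astrocytes. Summed astrocyte markers, such as the filament gene Gfap and the water channel gene Aqp4, reached 9397 ± 1304 CPM (n = 4) in buffer-treated astrocytes and 259 ± 28.7 CPM (n = 3) in buffer-treated microglia. The astrocyte cultures also held 7749 ± 3588 CPM of fibroblast and mural cell markers, against 2485 ± 854 CPM with ENV (n = 4 each). That marker list was not called with ENV. In the plot of principal components, PC1 carried 52.15% of the variance in microglia and 44.65% in astrocytes and parted treated from vehicle libraries in astrocytes. Microglial H2O replicate 3 (PC1 of -69.2) lay apart from H2O replicates 1 and 2 (23.3 and 22.3) and near the buffer libraries. LPS replicate 3 (PC1 of 63.5, PC2 of -75.8) likewise lay apart from LPS replicates 1 and 2 (131.3 and 125.8, 12.6 and 10.7). Its microglial markers summed to 7841.5 CPM, against 12043 and 11398 CPM. In astrocytes, PC2 (25.65%) was positive for replicates 1 and 2 of the LPS and H2O groups and negative for replicates 3 and 4.

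**Figure D1:**
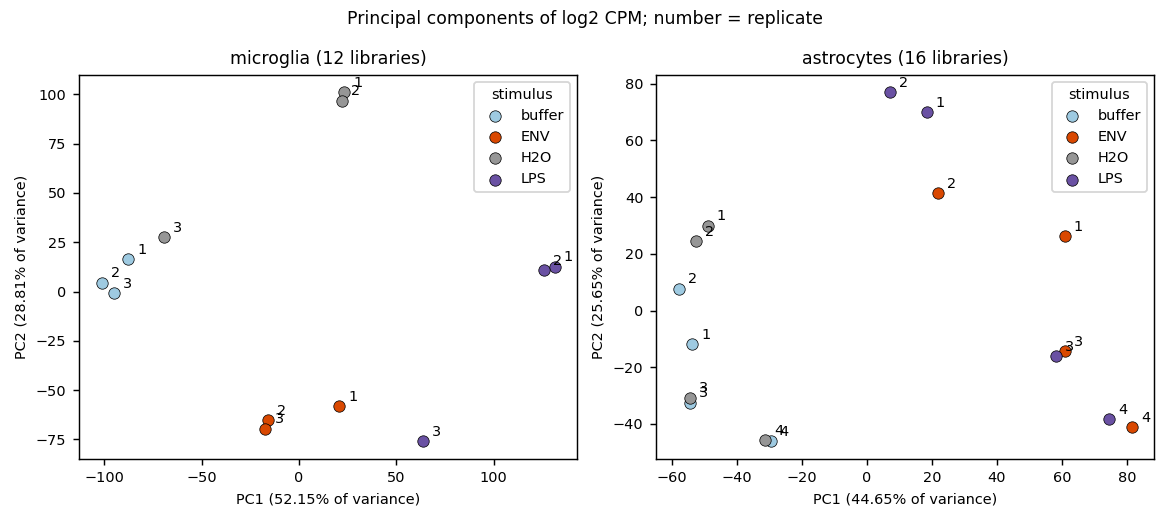
Principal components of log2 CPM per library, microglia left (n = 12) and astrocytes right (n = 16), with PC1 on the x axis, PC2 on the y axis, colour for the stimulus and the replicate number beside each point. Microglial H2O replicate 3 sits at -69.2 on PC1 while H2O replicates 1 and 2 sit at 23.3 and 22.3. Microglial LPS replicate 3 sits at 63.5 while LPS replicates 1 and 2 sit at 131.3 and 125.8, and astrocyte LPS replicates 1 and 2 sit at 70.0 and 77.1 on PC2 while LPS replicates 3 and 4 sit at -16.2 and -38.2.

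ENV raised chemokine, cytokine and interferon-stimulated transcripts in microglia. Lcn2, which encodes the iron-siderophore binder lipocalin-2, rose from 0.320 ± 0.0551 to 1241 ± 389.8 CPM (log2 change 11.90 ± 0.40, SE, adjusted p = 4.25e-05, n = 3 each). Nos2, the inducible nitric oxide synthase, rose from 0.122 to 160.3 ± 71.8 CPM (10.32 ± 0.70, adjusted p = 2.30e-04). Upp1, a uridine phosphorylase, rose by 9.98 ± 0.82 on the log2 scale (adjusted p = 3.88e-04) and Slpi, a leukocyte protease inhibitor, by 8.86 ± 0.55 (adjusted p = 1.84e-04). Retn, which encodes resistin, had no counts with buffer and was at least 107.8-fold higher with ENV (adjusted p = 0.00225). The chemokine Ccl5 had 1 count with buffer, which gave a ratio of 1412.5 (95% counting interval 253.1 to 55832.9). Among called genes of at least 10 CPM in the higher group and with groups that did not overlap, the largest falls were in Sost, a secreted Wnt antagonist (-6.21 ± 0.21, adjusted p = 4.25e-05), Tspan10 (-5.95 ± 0.41), the Ras exchange factor Rasgrp3 (-5.64 ± 0.28), Klra5 (-5.62), Lilrb3 (-5.35) and Card14 (-5.15). In all, 3972 of 12844 tested genes were called (2084 higher and 1888 lower). The count was 2548 without ENV replicate 1, 2466 without buffer replicate 2 and 2595 without ENV replicate 2.

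Lists of immune signalling genes were called as higher in these microglia. Other splits of these libraries called up to 17 lists, as many as the real one (17). List adjusted p-values are therefore descriptions, here and in the other comparisons. Among targets of NF-kB, the transcription factor downstream of TLR4, 20 of 25 rose and 0 fell, 22 adjusted over the list alone (median log2 change 0.95, list adjusted p = 2.36e-14, and adjusted p = 0.164 with an estimated correlation). Sod2 rose by 3.03, Map3k8 by 1.88, Bcl3 by 2.12 and Birc3 by 3.84. Of the interferon-stimulated genes, the antiviral programme switched on by type I interferon, 40 of 40 rose, 40 also adjusted over the list alone (median 3.31, adjusted p = 4.55e-32, and 0.181 with an estimated correlation), among them Parp14 (2.46), Ddx58 (3.35), Usp18 (6.0) and Oasl2 (3.83). Chemokines, which recruit leukocytes, rose in 14 of 18 cases, 15 adjusted over the list alone (median 4.32, adjusted p = 1.01e-18, and 0.0759 with an estimated correlation), with Ccl12 at 4.88, Cxcl3 at 8.56 and Cxcl2 at 4.86. For the cytokines, 12 of 20 rose and 3 fell, 13 and 5 adjusted over the list alone (median 2.20, adjusted p = 3.85e-06, and 0.0759 with an estimated correlation). Il1b rose from 276 ± 151 to 3075 ± 635 CPM (3.47 ± 0.41, adjusted p = 0.00146), Il10 by 3.18 and Tnf by 0.97 ± 0.19 (adjusted p = 0.00979), while Il6 went from 3 counts to 731 (ratio 268.0, interval 91.4 to 1303). In a joint fit of all 4 microglial groups Tnf was no longer called (adjusted p = 0.258, range over its alternatives 4.20e-05 to 0.258). Ccl2 rose by 4.11 ± 0.27 (adjusted p = 2.23e-04), Cxcl10 by 6.29 ± 0.86 (0.00248), Nfkbia by 1.36 (0.00105) and the LPS co-receptor Cd14 by 1.49 (0.00159), whereas Tlr4 was at -0.57 (0.0862), or called as lower without buffer replicate 3 (adjusted p = 8.61e-04).

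Transcripts of antigen presentation, nitric oxide synthesis and glycolysis rose with ENV in microglia, while cell cycle transcripts fell. MHC class I genes, which display intracellular peptides to T cells, rose in 13 of 16 cases, 15 adjusted over the list alone (median 1.47, adjusted p = 1.21e-07, and 0.308 with an estimated correlation), for example the activator Nlrc5 (3.14) and the peptide transporter Tap1 (1.79). For MHC class II and co-stimulation, 10 of 13 rose and 2 fell, 10 and 3 adjusted over the list alone (median 1.63, adjusted p = 0.00343, and 0.407 with an estimated correlation), with Cd40 at 1.32 and Cd80 at 1.99. In the list of nitric oxide, prostaglandin and oxidative burst genes, 12 of 16 rose, 13 adjusted over the list alone (median 2.42, adjusted p = 3.90e-18, and 0.0759 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, rose by 6.10, Gch1 by 3.21 and Acod1, which makes itaconate, by 6.94. Glycolytic genes rose in 13 of 16 cases, 14 up and 1 down adjusted over the list alone (median 1.78, adjusted p = 4.66e-16, and 0.0759 with an estimated correlation), with Hk1 at 1.92, Ldha at 2.52, Pgam1 at 1.76 and Pkm at 1.81. Cell cycle genes fell in 25 of 27 cases, 26 adjusted over the list alone (median -1.63, adjusted p = 5.94e-11, and 0.327 with an estimated correlation), among them the replication clamp Pcna (-1.65), Ccna2 (-2.28) and Bub1 (-1.99). Ribosomal protein genes went from 2.41 ± 0.542 to 1.54 ± 0.216% of counts. Mitochondrially encoded ones went from 2.96 ± 0.537 to 1.90 ± 0.360%. Markers of the oligodendrocyte lineage other than Cnp summed to 304.8 to 339.4 CPM in the buffer libraries and 82.4 to 170.8 CPM in the ENV libraries.

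The homeostatic and disease-associated microglial lists were called as lower with ENV, with members moving both ways. In the homeostatic list 9 of 20 fell and 2 rose, 10 and 2 adjusted over the list alone (median -0.44, adjusted p = 1.51e-05, and 0.164 with an estimated correlation). The lipid receptor Trem2 fell by 2.81, Pros1 by 2.52 and Gpr34 by 2.41. The purinergic receptor P2ry12 fell by 1.29 (adjusted p = 0.00287), and in a joint fit of all 4 microglial groups it was not called (adjusted p = 0.178, range over its alternatives 2.62e-08 to 0.178). Of the disease-associated genes, a phagocytic programme seen near damage, 12 of 19 fell and 3 rose, 12 and 3 adjusted over the list alone (median -0.96, adjusted p = 2.39e-05, and 0.0759 with an estimated correlation), with Lpl at -3.92, Ctsd at -1.57 and Cst7 at 3.75. The growth factor Igf1 fell from 772 to 134 CPM (-2.53 ± 0.53, adjusted p = 0.0124), a call lost without ENV replicate 1 (adjusted p = 0.0543). Arg1 rose from 2 counts to 47 (ratio 25.9, interval 6.77 to 220, adjusted p = 0.00743), with a fitted log2 change of 4.44, or 7.01 without buffer replicate 2. The macrophage mannose receptor Mrc1 (-0.43), complement C3 (0.68), Gfap (1.3) and the glutamate transporter Slc1a2 (0.88) were not called. The test was an edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Simulated 2-fold changes were recovered in 47.8% of cases and 4-fold changes in 87.9%, with far fewer genes changed than were called here.

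LPS raised interferon-stimulated, chemokine and cytokine transcripts in microglia. Cxcl11, a T cell attractant, rose from 0.0508 to 175 CPM (11.66 ± 0.67, adjusted p = 5.55e-04, n = 3 each), Lcn2 from 0.271 to 789.9 ± 568 CPM (11.52 ± 1.28; 0.00307), Nos2 from 0.838 to 1719 ± 1356 CPM (11.01 ± 1.03; 0.00190) and Upp1 by 10.48 ± 0.37 (1.94e-04). Cxcl10 rose from 2.67 to 1603 ± 286 CPM (9.23 ± 0.45, adjusted p = 3.91e-04). By the same rule the largest falls were in the peptide transporter Slc15a2 (-7.16), the oxysterol receptor Gpr183 (-6.72), Plxdc2 (-6.72), Sost (-6.28), Dhrs9 (-6.05) and Rasgrp3 (-5.85). The interleukin-23 receptor Il23r had no counts with H2O and was at least 220.9-fold higher with LPS (adjusted p = 0.0292), but was not called without H2O replicate 1 (0.0774), H2O replicate 2 (0.0758), LPS replicate 2 (0.0617) or H2O replicate 3 (0.0651). LPS changed 3647 of 12229 genes (1957 higher and 1690 lower). That count was 1351 without H2O replicate 1, 1580 without H2O replicate 2, 1744 without LPS replicate 2 and 2343 without H2O replicate 3.

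Interferon-stimulated genes gave the smallest list adjusted p in LPS-treated microglia: 40 of 41 rose, 40 adjusted over the list alone (median 3.94, adjusted p = 5.77e-82, and 0.0563 with an estimated correlation), such as Oasl (6.92), Usp18 (6.68) and Ifi44 (3.69). Chemokines rose in 14 of 18 cases, 14 adjusted over the list alone (median 5.05, adjusted p = 1.25e-12, and 0.185 with an estimated correlation), including Ccl5 (9.42) and Cxcl9 (6.63). NF-kB targets rose in 16 of 25 cases, 22 adjusted over the list alone (median 1.39, adjusted p = 3.22e-10, and 0.337 with an estimated correlation). Sod2 rose by 3.71, Nfkbie by 1.39, Birc3 by 4.58, Traf1 by 2.73 and Nfkbia by 1.98. Of the cytokines 13 of 22 rose and 1 fell, 15 and 1 adjusted over the list alone (median 2.57, adjusted p = 9.16e-04, and 0.337 with an estimated correlation), with the death ligand Tnfsf10 at 6.81 and Il18 at 1.83. MHC class I rose in 15 of 16 cases, 16 adjusted over the list alone (median 2.00, adjusted p = 6.45e-20, and 0.0563 with an estimated correlation), with RT1-S3 at 3.45 and Tapbp at 3.16. For MHC class II and co-stimulation 6 of 11 rose, 6 adjusted over the list alone (median 1.37, adjusted p = 0.0159, and 0.210 with an estimated correlation), with Cd40 at 3.37 and Cd274 at 2.12. Nitric oxide, prostaglandin and burst genes rose in 12 of 16 cases, 12 up and 1 down adjusted over the list alone (median 2.20, adjusted p = 6.41e-10, and 0.0563 with an estimated correlation), with Gch1 at 3.94 and Acod1 at 8.63. Glycolysis rose in 13 of 16 cases, 14 adjusted over the list alone (median 1.92, adjusted p = 3.80e-13, and 0.210 with an estimated correlation), with Hk1 at 2.57 and Eno1 at 2.17.

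The calls of several cytokine genes in LPS-treated microglia were lost without some single libraries. Tnf rose by 2.51 (adjusted p = 0.0465), but not without H2O replicate 1 (0.135), H2O replicate 2 (0.151), LPS replicate 2 (0.0796) or H2O replicate 3 (0.114), and its change was 1.31 without LPS replicate 3. Il1b rose by 4.27 (0.00988; 0.0539 without H2O replicate 1), Il6 by 9.47 (0.0113; 0.0576 without H2O replicate 1 and 0.0574 without H2O replicate 2), Ccl2 by 5.17 (0.0114; 0.0578 without H2O replicate 2) and Il10 by 4.81 (0.0137; 0.0689 without H2O replicate 1). Cxcl1 rose by 7.67 (0.0203, up to 0.0854 without H2O replicate 1, 2 or 3), or by 4.92 without LPS replicate 3. Csf3 rose by 11.38 (0.0242; 0.0991, 0.0953 and 0.108 without H2O replicate 1, 2 or 3), or by 7.23 without LPS replicate 3. Tlr4 fell by 1.13 (0.0424, up to 0.132 without H2O replicate 1, 2 or 3 or LPS replicate 1 or 2) and Mrc1 by 1.38 (0.0226, up to 0.0915 without H2O replicate 1 or 3 or LPS replicate 1 or 2), while C3 and Gfap were not called. The LPS co-receptor Cd14 rose by 2.24 (0.00601) and Arg1 by 7.96 ± 1.04 (0.00492).

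Cell cycle and homeostatic lists were called as lower in LPS-treated microglia. Cell cycle genes fell in 24 of 27 cases, 27 adjusted over the list alone (median -3.29, adjusted p = 7.04e-15, and 0.337 with an estimated correlation), with the proliferation marker Mki67 at -4.39, Mcm4 at -1.99 and Tpx2 at -2.23. Ribosomal protein genes went from 1.68 ± 0.191 to 0.988 ± 0.180% of counts. Mitochondrially encoded ones went from 2.84 ± 0.118 to 1.45 ± 0.0829%. The same lineage markers summed to 16.8, 17.1 and 179.5 CPM in H2O replicates 1 to 3 and to 5.04, 5.48 and 35.3 CPM with LPS. Homeostatic microglial genes fell in 8 of 19 cases, 11 adjusted over the list alone (median -1.80, adjusted p = 2.22e-05, and 0.383 with an estimated correlation), such as Pros1 (-3.74) and Tgfbr1 (-2.16). Disease-associated genes fell in 9 of 19 cases and rose in 3, 10 and 3 adjusted over the list alone (median -0.88, adjusted p = 0.00530, and 0.529 with an estimated correlation), with Cd9 at -4.69 and Lpl at -3.83. Igf1 fell from 745 to 27.2 CPM (-4.78 ± 0.61; 0.00465), while P2ry12 (-2.44; 0.0741) was called only without LPS replicate 3 (adjusted p = 0.00283). The biological coefficient of variation was 36.8% here and 22.8% for ENV, and simulated 2-fold changes were recovered in 5.97% of cases. Far fewer genes were changed in that simulation than were called here, so this share may understate the reach of the real test.

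ENV raised chemokine and cytokine transcripts in the astrocyte cultures. Ccl5 rose from 0.655 to 769 ± 282 CPM (10.10 ± 0.74, SE, adjusted p = 3.48e-04, n = 4 each), Nos2 from 0.0381 to 87.8 ± 116 CPM (10.90 ± 1.58; 0.00359) and Wfdc21 by 9.25 ± 0.92 (7.99e-04). The acute-phase gene Orm1 had 1 count with buffer, a ratio of 6011.2 (95% counting interval 1078.5 to 237467.6), as did the lymphocyte activation gene Cd69 (ratio 1401.5, 251.1 to 55394.3), and Csf3, the granulocyte growth factor, had 3 (ratio 1563.1, 534.5 to 7582.1). By the same rule the largest falls were in the synaptic vesicle gene Sv2c (-4.51), Gpr34 (-4.36), Plppr1 (-4.24 ± 0.39; 6.35e-04), Nkain4 (-4.16 ± 0.41; 7.67e-04), Synm (-4.04) and Krt16 (-3.99). Gfap, the main astrocyte filament, fell from 5691 ± 421 to 2065 ± 525 CPM (-1.46 ± 0.21; 0.00316) and Vim by 1.3 (0.00423), while Lcn2 rose from 17.1 ± 21.6 to 981.5 ± 625 CPM (5.83 ± 0.99; 0.00650). ENV changed 2670 of 14941 genes (1422 higher and 1248 lower), or 1692 without buffer replicate 1, 1690 without ENV replicate 1 and 1487 without buffer replicate 3.

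The shared inflammatory lists rose in the ENV-treated astrocyte cultures. Interferon-stimulated genes rose in 37 of 37 cases, 37 adjusted over the list alone (median 2.77, adjusted p = 8.71e-91, and 0.0233 with an estimated correlation), for example Irf7 (4.59), Rtp4 (2.71) and Mx1 (5.29). All 15 MHC class I genes tested rose, 15 adjusted over the list alone (median 1.77, adjusted p = 2.22e-39, and 0.0227 with an estimated correlation), including the immunoproteasome subunit Psmb9 (2.06 ± 0.09; 7.11e-05) and RT1-S3 (2.64). MHC class II and co-stimulation rose in 9 of 13 cases, 10 adjusted over the list alone (median 4.40, adjusted p = 2.24e-10, and 0.142 with an estimated correlation), with RT1-Da at 7.57, its activator Ciita at 5.03 and Cd74 at 6.80. NF-kB targets rose in 23 of 25 cases, 24 adjusted over the list alone (median 2.15, adjusted p = 2.09e-28, and 0.129 with an estimated correlation), with Slfn2 at 2.60, Tnip1 at 2.57 and Nfkbia at 2.94. Chemokines rose in 20 of 23 cases, 21 adjusted over the list alone (median 5.59, adjusted p = 6.23e-26, and 0.129 with an estimated correlation). Cxcl16 rose by 3.65, Ccl4 by 6.96, Ccl2 by 4.63 ± 0.57 (0.00188), Cxcl1 by 3.95 and Cxcl10 by 3.38. Cytokines rose in 16 of 23 cases, 16 adjusted over the list alone (median 2.82, adjusted p = 7.28e-16, and 0.129 with an estimated correlation), with Il1b at 7.07 ± 0.86 (0.00178), Il12b at 7.29, Il1a at 7.87, Il6 at 5.73 and Tnf at 3.28. Nitric oxide, prostaglandin and burst genes rose in 7 of 16 cases, 8 up and 1 down adjusted over the list alone (median 1.19, adjusted p = 7.81e-05, and 0.405 with an estimated correlation), with Gch1 at 3.47 and Acod1 at 6.70.

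The homeostatic astrocyte list was called as lower with ENV, with members moving both ways. Its genes, some of which serve glutamate and potassium uptake, fell in 12 of 23 cases and rose in 1, 16 and 2 adjusted over the list alone (median -0.84, adjusted p = 7.99e-08, and 0.129 with an estimated correlation). Ttyh1 fell by 2.32, Ntsr2 by 4.47, S100b by 1.72 and the potassium channel gene Kcnj10 by 1.98. The member that rose, named after its values were seen, was Aqp4 (1.33; 0.0205), a call lost without buffer replicate 1 (0.0568), 2 (0.0531) or 3 (0.0665) or ENV replicate 3 (0.0522). Of the A1 list, genes of a neurotoxic astrocyte state, 5 of 9 rose, 6 up and 1 down adjusted over the list alone (median 2.01, adjusted p = 1.66e-06, and 0.0384 with an estimated correlation), with Psmb8 at 1.73 and Gbp2 at 3.30. The pan-reactive list moved both ways, with 6 of 12 up and 3 down, 7 and 3 adjusted over the list alone (median 0.96, adjusted p = 0.211, and 0.469 with an estimated correlation). With the replicate number as a block this list was called (adjusted p = 0.0245, over alternatives from 0.0245 to 0.469). Microglial homeostatic genes, present at low level in these cultures, fell in 7 of 20 cases, 7 adjusted over the list alone (median -0.68, adjusted p = 4.05e-04, and 0.405 with an estimated correlation). Summed microglial markers went from 820, 99.8, 478 and 756 CPM in buffer replicates 1 to 4 to 392, 57.0, 295 and 461 CPM with ENV. That marker list was not called (adjusted p = 0.224), but was with the block (0.00718, over alternatives from 0.00718 to 0.789). Summed neuron markers went from 728 ± 140 to 366 ± 79.4 CPM in these cultures. The median neuron marker stood at 0.679 to 2.72 CPM in the buffer libraries and 0.881 to 2.30 CPM in the ENV libraries. The neuron list was not called. Igf1 fell by 2.64 (0.0154). C3 rose by 2.21 (adjusted p = 0.0393), a call lost without buffer replicate 1, 2 or 3 or ENV replicate 1, 3 or 4, and P2ry12 fell by 2.96 (0.0295), lost without buffer replicate 1, 3 or 4 or ENV replicate 1 or 3, with adjusted p up to 0.111 and 0.0827. Il10 had no counts with buffer and was at least 8.96-fold higher with ENV, while Tlr4, Cd14 (2.08; 0.0807), Mrc1 and Slc1a2 (0.86; 0.135) were not called. Cell cycle (0 of 27) and glycolysis (3 up and 1 down of 17) were not called as lists (adjusted p = 0.645 and 0.511).

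LPS raised chemokine and cytokine transcripts in astrocyte cultures. Ccl5 rose from 0.411 to 553 ± 512 CPM (10.40 ± 1.29, SE, adjusted p = 0.00773, n = 4 each), Il1a by 7.04 ± 0.71 (0.00408), Il1b from 2.16 to 194 ± 110 CPM (6.48 ± 0.58; 0.00291) and Ccl2 from 114.5 to 1951 ± 581 CPM (4.09 ± 0.48; 0.00688). Nos2 and Csf3 had 3 counts each with H2O, with ratios of 740.8 (95% counting interval 253.2 to 3595.2) and 720.5 (246.2 to 3496.6). The falls in Krt16 (-3.21 ± 0.47; 0.0110), Wscd2 (-3.18 ± 0.45; 0.00958) and Nkain4 (-3.10 ± 0.50; 0.0148) held without each library in turn. Other large changes did not: Wfdc21 (8.01) was lost without H2O replicate 1, 2 or 3 or LPS replicate 3 (adjusted p up to 0.0944), RT1-Da (8.01) without any H2O replicate or LPS replicate 3 or 4 (up to 0.117), LRRTM1 (-3.68) without H2O replicate 3 or 4 or any LPS replicate (up to 0.104), Lypd1 (-3.12) without H2O replicate 2 or any LPS replicate (up to 0.0757) and the Wnt and BMP inhibitor gene Sostdc1 (-3.18) without any of the 8 libraries (up to 0.122). LPS changed 785 of 14710 genes (389 higher and 396 lower). The count was 412 without H2O replicate 1, 442 without LPS replicate 1, 356 without H2O replicate 2, 236 without H2O replicate 3, 420 without LPS replicate 3, 513 without H2O replicate 4 and 417 without LPS replicate 4, and 2611 with the replicate number as a block.

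Interferon-stimulated and chemokine genes gave the smallest list adjusted p in LPS-treated astrocyte cultures. Of the interferon-stimulated genes 31 of 36 rose, 35 adjusted over the list alone (median 2.39, adjusted p = 3.07e-54, and 0.143 with an estimated correlation), with Parp14 at 2.05, Mx1 at 4.94, Oasl at 3.99 and Irf7 at 4.38. Chemokines rose in 16 of 23 cases, 21 adjusted over the list alone (median 5.25, adjusted p = 3.05e-31, and 0.143 with an estimated correlation), such as Cxcl11 (6.50 ± 0.51; 0.00253) and Cxcl16 (3.48). NF-kB targets rose in 15 of 25 cases, 24 adjusted over the list alone (median 2.16, adjusted p = 1.65e-23, and 0.274 with an estimated correlation), such as Nfkb2 (2.28) and Slfn2 (2.18). Cytokines rose in 12 of 21 cases, 15 adjusted over the list alone (median 2.56, adjusted p = 1.45e-17, and 0.143 with an estimated correlation). MHC class I rose in 14 of 15 cases, 14 adjusted over the list alone (median 1.53, adjusted p = 2.43e-21, and 0.184 with an estimated correlation), with Psme2 at 1.29 and Tap1 at 1.53. MHC class II and co-stimulation rose in 4 of 9 cases, 5 adjusted over the list alone (median 2.02, adjusted p = 7.96e-04, and 0.361 with an estimated correlation). Nitric oxide, prostaglandin and burst genes rose in 3 of 16 cases and fell in 1, 6 and 1 adjusted over the list alone (median 0.88, adjusted p = 1.92e-04, and 0.356 with an estimated correlation), with Acod1 at 5.61. A1 genes rose in 3 of 9 cases, 4 up and 1 down adjusted over the list alone (median 1.56, adjusted p = 7.96e-04, and 0.299 with an estimated correlation), with Gbp2 at 2.96.

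The homeostatic astrocyte list was called as lower with LPS. Its genes fell in 3 of 22 cases, 12 adjusted over the list alone (median -0.76, adjusted p = 3.37e-06, and 0.330 with an estimated correlation), with Ttyh1 at -1.97 (adjusted p = 0.0203, and up to 0.0709 without LPS replicate 1, H2O replicate 3 or LPS replicate 4). Fibroblast and mural cell markers summed to 3387, 5774, 9855 and 2865 CPM in H2O replicates 1 to 4 and to 1908, 2320, 3420 and 1887 CPM with LPS. That list was not called (adjusted p = 0.0515) other than with the block (0.00184, over alternatives from 0.00184 to 0.399). Microglial homeostatic genes fell in 3 of 20 cases, 8 adjusted over the list alone (median -0.87, adjusted p = 3.36e-06, and 0.274 with an estimated correlation). The microglial marker list was called as lower with no member called (0 of 12; 2 down adjusted over the list alone, median -0.49, adjusted p = 0.0114, and 0.623 with an estimated correlation). Summed neuron markers went from 649 ± 220 CPM with H2O to 346 ± 82.3 CPM with LPS. The median neuron marker stood at 0.497 to 1.99 CPM in the H2O libraries and 1.10 to 2.41 CPM in the LPS libraries. The neuron list was not called. Vim fell by 1.14 (0.0114). Lcn2 went from 17.1 to 703 ± 718 CPM (5.36 ± 1.37; 0.0645), Gfap from 4459 to 1681 CPM (-1.41 ± 0.49; 0.145) and C3 by 2.19 (0.244), none of them called. With the replicate number as a block these 3 were called (adjusted p = 0.00320, 0.00803 and 0.0129, over alternatives from 2.35e-04 to 0.188, 1.54e-04 to 0.317 and 0.0129 to 0.456). Without pairing Lcn2 and Gfap were called by DESeq2 (2.35e-04 and 0.0261) and in the joint fit (0.0152 and 0.0299). Il6 rose by 4.79 (0.0141; 0.0602 without H2O replicate 3) and Cxcl10 by 3.16 (0.0211, up to 0.0811 without H2O replicate 1, 2 or 3). Tnf (2.78; 0.0333) and Nfkbia (2.77; 0.0266) were each lost without H2O replicate 1, 2 or 3 or LPS replicate 3 or 4 (up to 0.103 and 0.0946). Cxcl1 (3.67; 0.0302) was lost without H2O replicate 1, 2 or 3 or LPS replicate 1, 3 or 4 (up to 0.106) and Igf1 (-2.37; 0.0294) without H2O replicate 1 or 3 or any LPS replicate (up to 0.0766). Simulated 2-fold changes were recovered in 23.9% of cases and 4-fold changes in 80.3%, with fewer genes changed than were called here.

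**Figure D2:**
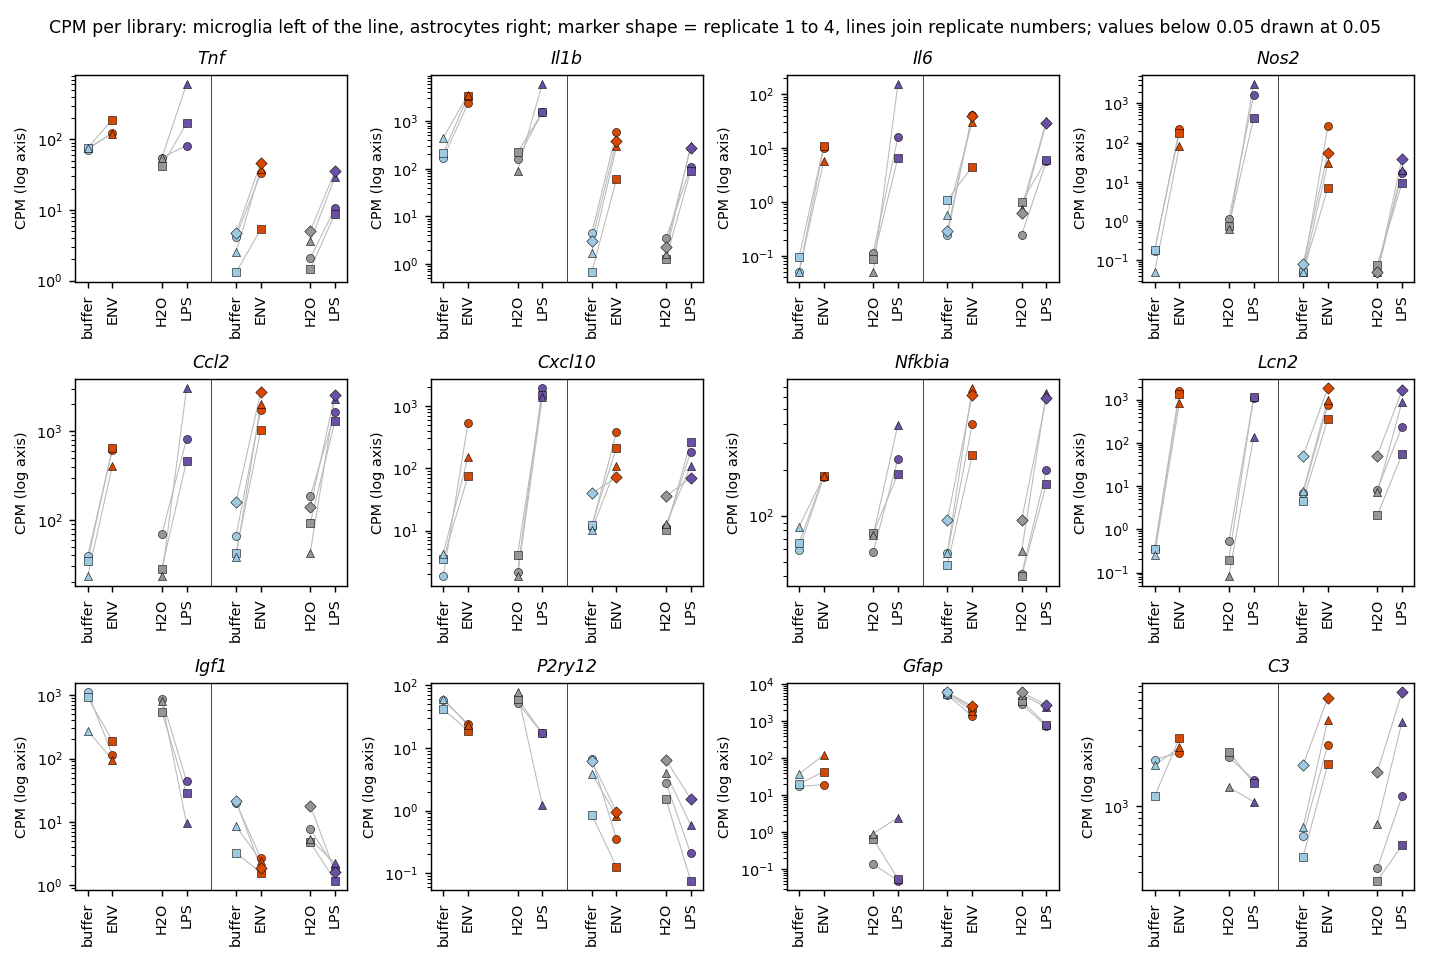
CPM per library on a log axis for 12 panel genes, microglia left and astrocytes right of the vertical line, with marker shape for the replicate and grey lines joining equal replicate numbers. Lcn2 rose from 0.320 to 1241 CPM in ENV-treated microglia and from 17.1 to 981.5 CPM in ENV-treated astrocytes, whereas Gfap fell from 5691 to 2065 CPM in the latter.

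**Figure D3:**
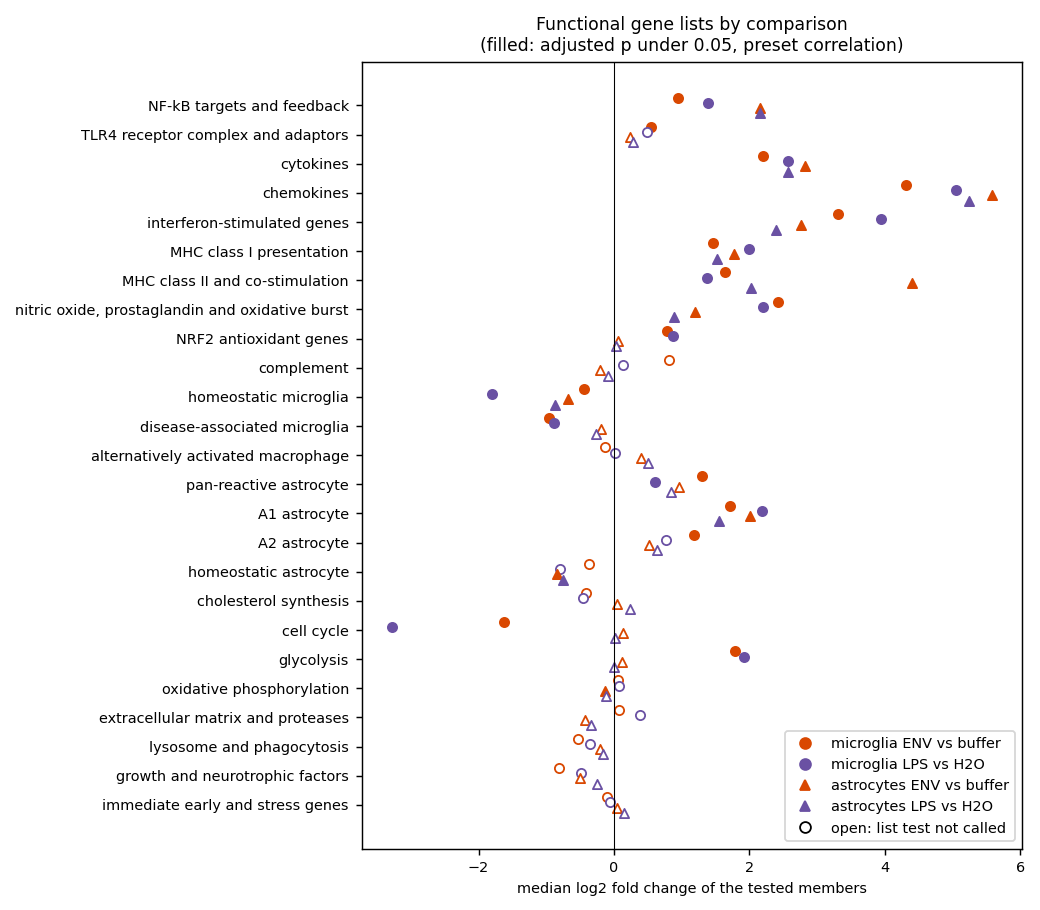
Median log2 fold change of each of the 25 functional gene lists (x axis) in the 4 comparisons, filled where the list test with a preset correlation gave an adjusted p under 0.05. Chemokine medians ran from 4.32 to 5.59, while the cell cycle medians of -1.63 and -3.29 in microglia stood against values near 0 in astrocytes.

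Genes called for both ENV and LPS moved in the same direction within each cell type, other than 1 gene in microglia. Of the genes tested for both, 2048 rose and 1779 fell with ENV in microglia and 1383 rose and 1230 fell in astrocytes. In microglia 1401 genes rose and 1079 fell with both stimuli and 1 moved in opposite directions, against 325.7 and 247.8 expected by independent overlap among 11984 genes tested in both. That gene, Sh3bp4, was named after its values were seen (-0.57 with ENV, adjusted p = 0.0437, and 1.26 with LPS, 0.0135). Its ENV call was lost without buffer replicate 1 or 2 or any ENV replicate (up to 0.143) and its LPS call without H2O replicate 2 (0.0579). In astrocytes 364 rose and 340 fell with both and 0 were opposed (36.7 and 32.6 expected among 14617). Across genes, which are not independent replicates, the log2 changes correlated at r = 0.893 in microglia and r = 0.948 in astrocytes. Astrocyte ENV and LPS replicate 4 lay closer together (variance 3.32 times that of counting) than any 2 libraries of the same astrocyte group (lowest 6.43). So did buffer and H2O replicate 3 (2.85) and replicate 4 (2.58). The astrocyte ENV and LPS sets may therefore not be separate evidence. Since buffer and H2O astrocyte libraries of equal number correlated (0.276 to 0.770), the sets were also compared across numbers: with ENV replicates 1 and 2 set against LPS replicates 3 and 4 the correlation was r = 0.842 with 0 genes opposed, or r = 0.684 the other way round with 10 opposed (304 rose and 235 fell with both). Direct tests of the ENV response minus the LPS response with edgeR called 0 genes in microglia (937 at an unadjusted p under 0.05, and 67 with DESeq2) and 0 in astrocytes (76 and 0). Leaving out microglial LPS replicate 1, LPS replicate 2 or H2O replicate 3 gave 1, 4 and 1 genes, named after their values were seen: a gene without a symbol, then Ccrl2, Hcar2, Plpp3 and Smpd1, then Chadl. The estimates in microglia were -2.91 ± 0.90 for Cxcl10 (adjusted p = 0.666), 2.30 ± 0.81 for Igf1 (0.689) and 0.44 ± 1.24 for Lcn2 (0.968). In astrocytes they were 0.59 ± 0.91 for Il1b and -0.05 ± 0.54 for Gfap (adjusted p = 1 for both). These tests had limited reach: 44.26% of the 2481 genes called for both stimuli in microglia and 52.7% of the 704 in astrocytes had a 95% interval for the difference within 2-fold. With a replicate block shared by both sets the astrocyte share was 62.6%.

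**Figure D4:**
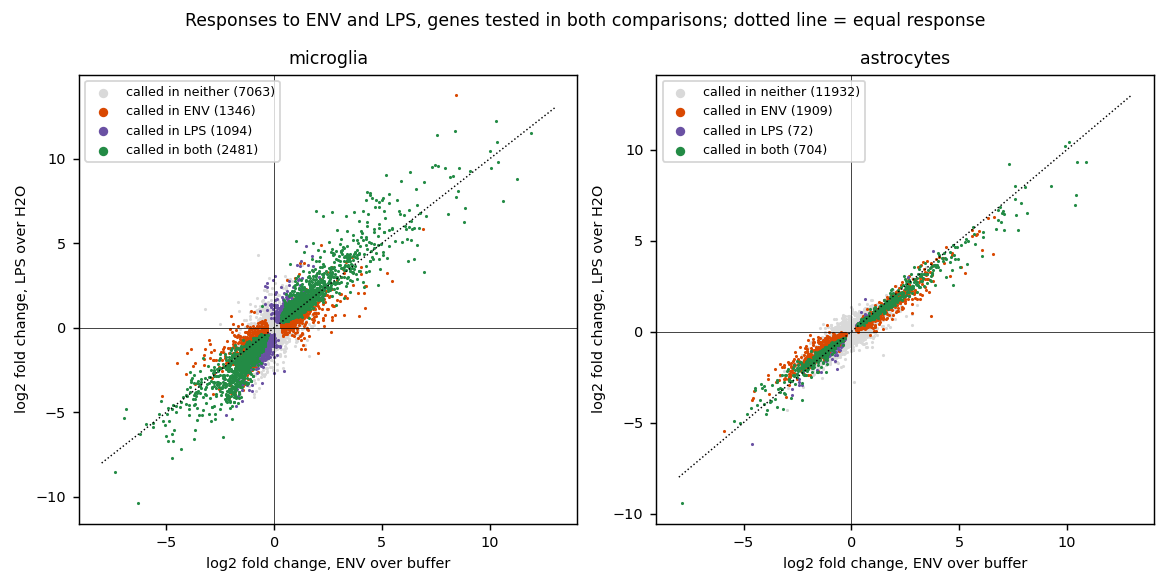
Log2 fold change with ENV (x axis) against that with LPS (y axis) for each gene tested in both comparisons, microglia left and astrocytes right, coloured by where the gene was called. The 2481 genes called in both in microglia and the 704 in astrocytes lie along the dotted line of equal response, with 1 and 0 genes of opposite direction.

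Genes called in both microglia and astrocytes moved in the same direction more often than in opposite ones, while the interaction test called differences in response for many genes. With ENV 510 genes rose and 243 fell in both cell types and 117 moved in opposite directions, against 191.7, 129.0 and 316.7 expected (11331 genes, r = 0.506 across genes). With LPS the numbers were 216, 46 and 21, against 51.2, 28.9 and 78.0 (10667 genes, r = 0.50). The ENV response minus its astrocyte counterpart was called for 1998 of 13378 genes (919 higher and 1079 lower in microglia), and the LPS difference for 1656 of 13284 (707 and 949). Upp1 rose far more in microglia for both stimuli (difference 7.67 ± 1.12 with ENV, adjusted p = 8.26e-04, and 8.31 ± 1.14 with LPS). So did the B cell surface protein gene Cd22 with ENV (6.29 ± 1.06, adjusted p = 0.00205), which rose by 1.44 in microglia and fell by 4.86 in the astrocyte cultures. Summed microglial markers in those cultures went from 538 to 301 CPM with ENV, so the cells behind the fall of Cd22 are not known. The dendritic cell marker Cd83 went the other way, down by 1.71 in microglia and up by 4.73 in astrocytes (difference -6.46 ± 0.96), as did the retinol dehydrogenase family gene Dhrs9 (-6.44 ± 0.81 with ENV and -7.58 ± 1.00 with LPS). Differences of similar size were seen for Cd69 (-7.59 ± 1.29), Ubxn10 (-6.66 ± 0.80), the phosphodiesterase Pde2a (-5.80 ± 0.91) and Olr1585 (7.07 ± 1.52) with ENV. With LPS they were seen for Plac8 (10.76 ± 1.13), the adrenergic receptor Adra2a (9.46 ± 1.12), Vwa1 (6.93 ± 0.99), Ubxn10 (-7.51 ± 1.01), Rassf9 (-6.95 ± 1.33) and the lipid regulator Pparg (-5.73 ± 1.08). Chadl differed by 7.23 with LPS, or 11.42 without microglial H2O replicate 3.

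Of the panel genes, Lcn2 rose more in microglia with ENV (difference 6.06 ± 1.24, adjusted p = 0.00627), from a baseline that was lower than in astrocytes, and Cxcl10 rose more in microglia with LPS (6.04 ± 0.79; 8.26e-04). The Gfap difference with ENV was 2.75 (0.0182), or 0.0527 and 0.0530 in adjusted p without microglial buffer replicate 1 or 2, and 1.77 on the log2 scale without ENV replicate 3. Il1b rose less in microglia with ENV (-3.61; 0.0235), which was lost without microglial ENV replicate 1 (0.0646) or 2 (0.0509), microglial buffer replicate 3 (0.0510) or astrocyte buffer replicate 3 (0.0502). The Nfkbia difference of -1.59 (0.0311) was lost without microglial ENV replicate 1, 2 or 3, microglial buffer replicate 2 or 3, astrocyte buffer replicate 1, 2 or 3 or astrocyte ENV replicate 3 (0.0550 to 0.0774). Also in the ENV set, Sstr4 (7.67) was lost without microglial ENV replicate 1 (0.0987) or 2 (0.0645), and Plac8 (7.21) without astrocyte buffer replicate 1 (0.0862). In the LPS set, Cd74 (-5.80; 0.0415) was lost without each of the 14 libraries other than astrocyte LPS replicates 1 and 2 (0.0530 to 0.0992), and Igf1 (-2.45; 0.0493) without each other than microglial LPS replicate 1 and astrocyte H2O replicate 4 (0.0561 to 0.124). The median change of all genes was -0.12 in the LPS difference and moved to -0.03 under DESeq2 size factors, with which 913 genes were higher and 759 lower in microglia. In the ENV difference those size factors gave 1062 higher and 902 lower, and without astrocyte buffer replicate 2 the numbers were 962 and 642. The balance of directions was thus not fixed by these data in either. Microglial and astrocyte libraries came as separate sets, so cell type and set cannot be told apart.

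The buffer and H2O vehicles were compared as a measure of how far the ENV and LPS sets lay apart before stimulation. With edgeR 0 of 12900 genes were called in microglia (smallest edgeR adjusted p = 0.0629, 1946 at an unadjusted p under 0.05), and 679 with DESeq2. In astrocytes 0 of 14876 were called (125 at an unadjusted p under 0.05, and 0 with DESeq2). Without microglial H2O replicate 3 the edgeR count was 1653.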

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

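The comparison of astrocyte levels with those of the microglial cultures, the slopes within replicates 1 and 2 and 3 and 4, and the oligodendrocyte-lineage tests were chosen only after the results were seen. In astrocyte groups of 4 libraries, 118 values were tested for a library far from the other 3, and 8 lay past the critical value, where chance gives about 1 in 20 groups, or 5.9. In 7 of the 8 the library was replicate 4 of a vehicle group. Buffer replicate 4 and H2O replicate 4 lay closer together (variance 2.58 times that of counting) than any 2 libraries of the same astrocyte group (lowest 6.43). Their values may therefore repeat each other and are not separate evidence. Buffer and H2O replicate 3 (2.85) and ENV and LPS replicate 4 (3.32) also lay closer than that. With buffer, replicate 4 stood at 165.5 CPM for Cxcl1 (others 18.1 to 41.5, gap over range 0.842), 39.4 CPM for Cxcl10 (10.3 to 12.5, 0.926), 49.5 CPM for Lcn2 (4.62 to 7.54, 0.935) and 2107.5 CPM for C3 (393.5 to 674.7, 0.836). With H2O it stood at 164.6 CPM for Cxcl1 (27.9 to 38.0, 0.926), 35.7 CPM for Cxcl10 (10.1 to 12.6, 0.903) and 50.8 CPM for Lcn2 (2.09 to 8.28, 0.873). With LPS, summed neuron markers reached 468.2 CPM in replicate 3 (288.1 to 317.2, 0.839).

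The ENV response differed between the cell types for 1998 genes by the interaction test, in which microglia minus astrocytes is given here as a log2 difference. Upp1 (7.67), Olr1585 (7.07), Cd22 (6.29) and Lcn2 (6.06) were higher, and Cd69 (-7.59), Ubxn10 (-6.66), Cd83 (-6.46), Dhrs9 (-6.44) and Pde2a (-5.80) lower. These held without each library in turn. Sstr4 (7.67) was lost without microglial ENV replicate 1 (adjusted p = 0.0987) or 2 (0.0645), and Plac8 (7.21) without astrocyte buffer replicate 1 (0.0862). Gfap (2.75) was lost without microglial buffer replicate 1 (0.0527) or 2 (0.0530) and was at 1.77 without microglial ENV replicate 3. Il1b (-3.61) was lost without microglial ENV replicate 1 or 2, microglial buffer replicate 3 or astrocyte buffer replicate 3 (0.0502 to 0.0646). Nfkbia (-1.59) was lost without microglial ENV replicate 1, 2 or 3, microglial buffer replicate 2 or 3, astrocyte buffer replicate 1, 2 or 3 or astrocyte ENV replicate 3 (0.0550 to 0.0774). Of 60 relabelled splits 2 gave as many genes, the real one included (highest other 2804). Of the 64 that swapped libraries within pairs 3 did so (highest 4396), and 21 other than the real one called genes. Relabelling also removes the treatment effects themselves, so these splits cannot decide whether chance gave the count of differences. With the replicate number as a block the count was 3314.

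With LPS the interaction test called 1656 genes. Plac8 (10.76), Adra2a (9.46), Upp1 (8.31), Vwa1 (6.93) and Cxcl10 (6.04) were higher in microglia, and Dhrs9 (-7.58), Ubxn10 (-7.51), Rassf9 (-6.95) and Pparg (-5.73) lower. Chadl (7.23) was at 11.42 without microglial H2O replicate 3. Cd74 (-5.80) was lost without each library other than astrocyte LPS replicates 1 and 2 (adjusted p = 0.0530 to 0.0992), and Igf1 (-2.45) without each other than microglial LPS replicate 1 and astrocyte H2O replicate 4 (0.0561 to 0.124). Of 60 relabelled splits 3 gave as many genes (highest other 3609), so chance could not be excluded for this count. Among the 64 swaps within pairs 7 gave as many, and the blocked count was 3029.

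Cytokine and chemokine genes rose in the astrocyte cultures (37 members, 36 listed for both cell types), although these still held microglial transcripts after the microglia had been shaken off. Summed microglial markers stood at 0.455 to 4.06% of their level in microglia under the same stimulus (12 markers, 6 of them also in other lists, led by Csf1r at 121.4 and 95.8 CPM and C1qb at 81.0 and 66.2 CPM with buffer and H2O). Il19, Lif, Csf1, Ccl5, Ccl19, Ccl20, Cxcl6, Cxcl9, Cxcl12, Cxcl16 and Cx3cl1, 11 members, lay above every microglial library of the same stimulus in each treated astrocyte library of a stimulus that raised them, which argues against microglial RNA as their whole source. Whether astrocytes or fibroblasts and mural cells were the source was not tested. Markers of the latter summed to 7749 CPM with buffer and 5470 CPM with H2O in these cultures. For the 32 members above the level that the marker share brings in each treated library of a stimulus that raised them, these 11 included, the median log2 slope on the microglial marker sum over 8 treated libraries was 0.848 (quartiles 0.396 to 1.063). It was 0.488 (0.18 to 0.706) for Il10, Ebi3, Tnfsf10 and Ccl9, which were above that level in 3 of 4, 3 of 8, 7 of 8 and 1 of 4 such libraries. Of the other 21, Cxcl1, Csf2, Ccl2 and Ccl7 had means above those of the microglial cultures with both stimuli (2853 and 319%, 2279 and 183%, 365 and 148% and 346 and 111% with ENV and LPS). This argues against microglial RNA as their whole source too, although not every library lay above every microglial one. Means exceeded those of microglia with ENV alone for Csf3 (618%), Cxcl11 (434%), Il12b (352%), Il6 (346.5%), Cxcl3 (282.5%), Cxcl2 (203%) and Lta (110.5%). With LPS these genes stood at 7.49 (Lta) to 53.2% (Il12b). Their slopes ran from 0.204 (Cxcl11) to 1.27 (Csf3), so their source stays open. For the rest of the 21, these genes included, residual microglia and other cells of these cultures cannot be told apart as the source. The same holds for Il10, Ebi3, Tnfsf10 and Ccl9. The median slopes of the 11 and the 21 were 0.808 and 0.900 over the 8 libraries, and 0.373 and 0.852 within replicates 1 and 2 and 3 and 4, so they stood apart only in the form chosen after the results were seen.

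Cell cycle transcripts in microglia fell from a sum of 1352 ± 115 to 404 ± 157 CPM with ENV and from 1142 ± 444 to 170 ± 26 CPM with LPS (SD, n = 3 each). Loss of dividing astroglia from the cultures would cover 8.26% of the fall with ENV (7.51 to 9.28 over vehicle libraries) and 7.2% with LPS (3.21 to 14.5), which argues against it as the whole cause (10 astrocyte markers, all also in other lists, led by Slc1a3 at 206.8 and 134.5 CPM in buffer- and H2O-treated microglia after the CD11b/c sort). Markers of the oligodendrocyte lineage (12, none in another list) were summed without Cnp, which was higher with both stimuli. An earlier form of the test, with Cnp, was set aside after its result was seen. In it the log2 change of the sum lay 1.18 and 2.99 above that of the cell cycle sum with ENV and LPS. In LPS replicates 1 and 2, whose H2O partners held 16.8 and 17.1 CPM of the markers without Cnp, their loss would cover at most 18.4% of the fall. That share takes the highest cell cycle sum per marker sum of the vehicle libraries rich in these markers (9.05, H2O replicate 3). It gives all cell cycle transcripts of that library to the lineage. Replicate 3 reached 91.2%, but with its own ratio, so its value was high by construction and cannot decide there. With ENV the lineage sum fell by 0.52 less than the cell cycle sum on the log2 scale (-0.45 to 1.5 at 2 standard errors), so there loss of lineage cells and slower division of microglia cannot be told apart. Slower division of microglia may account for the fall with LPS, a hypothesis found and examined on the same libraries, against which loss of dividing microglia was not tested.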

How the results depend on the processing

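Overlaps are given as genes risen and fallen in both. Alternatives that used replicates 1 and 2 or 3 and 4 alone, or a block shared by both sets, were chosen after seeing the data. No called value turned its direction under any alternative run. The causes of the shifts were not tested, apart from fewer libraries or a stricter threshold where that was the alternative. An absolute log2 change of at least 1 gave 2049 genes for microglial ENV, 2234 for microglial LPS, 1295 for astrocyte ENV, and overlaps of 707 and 657 (microglia, ENV with LPS), 254 and 222 (astrocytes, ENV with LPS), 243 and 82 (ENV, microglia with astrocytes) and 151 and 27 (LPS). The replicate block gave 4348 for astrocyte ENV, 2611 for astrocyte LPS, 1 (Adamts4) for microglial ENV minus LPS, 3314 and 3029 for microglia minus astrocytes with ENV and LPS, and overlaps of 997 and 1283 (astrocytes), 801 and 594 (ENV) and 449 and 249 (LPS). DESeq2 gave 2049 for astrocyte LPS, 67 for microglial ENV minus LPS, 2720 for LPS in microglia minus astrocytes, 679 for the microglial vehicles, and overlaps of 860 and 888 (astrocytes), 700 and 436 (ENV) and 469 and 195 (LPS). The joint fit gave 1736 for astrocyte LPS. Replicates 1 and 2 alone gave 372 for astrocyte ENV and 2970 for astrocyte LPS, and replicates 3 and 4 gave 950 for astrocyte ENV. With LPS and H2O replicates 1 and 2 alone, microglial ENV minus LPS gave 8, and with H2O replicates 1 and 2 the microglial vehicles gave 1653. Overlaps of astrocyte ENV replicates 1 and 2 were 162 and 132 with LPS replicates 1 and 2 and 114 and 54 with LPS replicates 3 and 4. Camera with an estimated correlation called 0, 0, 3 and 0 lists (microglial ENV and LPS, astrocyte ENV and LPS), against 17, 14, 13 and 11 with the preset one.

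Leaving out each library in turn gave 2466 to 5282 genes for microglial ENV, 1351 to 3986 for microglial LPS, 1487 to 2869 for astrocyte ENV, 236 to 681 for astrocyte LPS, 0 to 4 for microglial and 0 to 0 for astrocyte ENV minus LPS, and 1414 to 2287 and 1105 to 1820 for microglia minus astrocytes with ENV and LPS. Of the values of named genes so obtained, 813 of 882, 752 of 846, 1056 of 1152 and 922 of 1120 kept direction and side of the threshold in the 4 treated comparisons, and 64, 79, 86 and 187 lost their call. Under the DESeq2 test 142 of 147, 122 of 135, 136 of 144 and 103 of 140 named genes kept both, with 3, 13, 8 and 37 newly called. Under DESeq2 size factors 146 of 147, 141 of 141, 143 of 144 and 139 of 140 did, without a filter 144, 139, 142 and 137, and with the block 139, 131, 129 and 99. With the block 6, 7, 14 and 40 were newly called and 2, 2, 0 and 0 lost their call. Every list kept its result under DESeq2 size factors (32, 32, 32 and 31), and 3, 2, 5 and 2 were newly called by fry, which lost 4 in astrocyte LPS. Alternatives for normalized values did not apply, since the files hold counts, and were not run. In simulations 2-fold changes were recovered in 47.8%, 5.97%, 59.7% and 23.9% of cases in the 4 treated comparisons and 1.5-fold changes in 1.49%, 0%, 13.4% and 2.99%. Fewer genes were changed there than were called in the treated comparisons, so these shares may understate their reach. For differences between responses 2-fold changes were found in 5.97% to 22.4%, so many small differences could be missed.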

Other observations

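The blocked ratio of astrocyte calls and the test of a weaker LPS response were chosen only after the result was seen. Further lists were called in microglia beside the inflammatory ones. With ENV, NRF2 antioxidant genes rose in 9 of 14 cases and fell in 1, 10 and 1 adjusted over the list alone (median 0.78, adjusted p = 3.48e-04, and 0.0759 with an estimated correlation), among them Txnrd1 (1.38) and the cystine transporter Slc7a11 (5.30). Genes first listed for reactive astrocytes rose in these microglia: 6 of 11 pan-reactive members (1 fell, 7 and 1 over the list alone, median 1.3, adjusted p = 1.37e-05, and 0.0759 with an estimated correlation), 6 of 9 A1 members (7 and 1, median 1.72, 2.39e-04, and 0.181 with an estimated correlation) and 5 of 8 A2 members (2 fell, 6 and 2, median 1.19, 1.95e-04, and 0.0961 with an estimated correlation). Members were Steap4 (3.94), Osmr (2.74), Gbp2 (3.36) and Ggta1 (1.72). The TLR4 receptor complex and adaptors rose in 6 of 12 cases, 6 over the list alone (median 0.54, adjusted p = 0.0214, and 0.262 with an estimated correlation), with Tirap at 1.13, and granulocyte and monocyte markers in 3 of 4, 3 over the list alone (median 2.22, 0.0251, and 0.271 with an estimated correlation), with Camp at 2.55 and Csf3r at 1.88. With LPS, NRF2 genes rose in 6 of 14 cases, 6 over the list alone (median 0.88, adjusted p = 0.0235, and 0.561 with an estimated correlation), pan-reactive genes in 4 of 11 with 1 down, 4 and 1 over the list alone (0.60, 0.0107, and 0.248 with an estimated correlation) and A1 genes in 6 of 9, 6 over the list alone (2.19, 1.46e-06, and 0.0563 with an estimated correlation), with Osmr at 4.31 and Gbp2 at 4.33.

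In ENV-treated astrocyte cultures 3 further lists were called as lower. Astrocyte markers fell in 5 of 10 cases and rose in 1, 6 and 3 over the list alone (median -0.79, adjusted p = 0.00985, and 0.281 with an estimated correlation). Ependymal and choroid plexus markers fell in 2 of 3, 3 over the list alone (-1.85, 0.00572, and 0.129 with an estimated correlation), and oxidative phosphorylation in 3 of 27, 1 over the list alone (-0.13, 0.0461, and 0.652 with an estimated correlation, or 0.161 with the replicate block and 0.0293 to 0.652 over its alternatives). Single genes moved strongly in lists that were not called: the metalloproteinases Mmp9 (5.45 in microglia with ENV, 6.40 in astrocyte cultures with LPS) and Mmp3 (8.06 in astrocyte cultures with ENV), complement factor Cfb (3.95) and C4b (3.12) in the latter, and in microglia with ENV C1r (4.62), Pparg (-4.97), Sparc (-2.80) and the lysosomal protease Ctsa (-1.17). With LPS, Sparc (-3.43), Ctsa (-1.42), Egr1 (-2.12) and Scarb1 (-2.0) fell in microglia and Klf4 (1.75), Ddit3 (1.54) and Hif1a (0.83) rose in astrocyte cultures.

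The remaining lists were not called by camera with the preset correlation, each given as members up and down of those tested and the adjusted p. In microglia with ENV they were complement (6 and 2 of 14, 0.122), alternatively activated macrophages (3 and 2 of 12, 0.844), homeostatic astrocytes (1 and 2 of 18, 0.542), cholesterol synthesis (1 and 6 of 23, 0.0968), oxidative phosphorylation (2 and 0 of 25, 0.542), extracellular matrix (7 and 2 of 23, 0.178), lysosome (7 and 12 of 24, 0.158), growth factors (2 and 6 of 14, 0.158), immediate early genes (5 and 5 of 16, 0.850) and markers of microglia (3 and 1 of 12, 0.490), astrocytes (0 and 1 of 9, 0.844), oligodendrocyte lineage (1 and 3 of 10, 0.125), neurons (0 and 2 of 6, 0.646), endothelium (3 and 1 of 7, 0.673) and fibroblasts (1 and 2 of 5, 0.125). In microglia with LPS they were TLR4 (4 and 1 of 12, 0.0883), complement (3 and 2 of 14, 0.520), alternatively activated macrophages (4 and 2 of 13, 0.751), A2 (4 and 2 of 8, 0.307), homeostatic astrocytes (0 and 0 of 12, 0.751), cholesterol synthesis (1 and 6 of 23, 0.167), oxidative phosphorylation (2 and 0 of 25, 0.666), extracellular matrix (4 and 4 of 22, 0.751), lysosome (3 and 5 of 24, 0.285), growth factors (1 and 1 of 12, 0.288), immediate early genes (3 and 3 of 17, 0.674) and markers of microglia (3 and 1 of 12, 0.751), astrocytes (0 and 0 of 5, 0.833), oligodendrocyte lineage (1 and 1 of 8, 0.751), neurons (0 and 0 of 3, 0.901), endothelium (1 and 0 of 7, 0.695), fibroblasts (0 and 3 of 5, 0.285) and granulocytes (1 and 0 of 4, 0.0842).

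In astrocyte cultures with ENV the lists not called were TLR4 (1 and 0 of 13, 0.226), NRF2 (2 and 1 of 16, 0.723), complement (7 and 1 of 17, 0.0631), disease-associated microglia (2 and 7 of 19, 0.348), alternatively activated macrophages (4 and 1 of 11, 0.194), A2 (3 and 1 of 13, 0.194), cholesterol synthesis (2 and 3 of 25, 0.928), extracellular matrix (6 and 4 of 27, 0.928), lysosome (0 and 5 of 24, 0.0770), growth factors (1 and 4 of 21, 0.0907), immediate early genes (5 and 1 of 18, 0.194) and markers of microglia (0 and 1 of 12, 0.224), oligodendrocyte lineage (0 and 2 of 10, 0.321), neurons (1 and 2 of 6, 0.348), endothelium (0 and 0 of 7, 0.711) and fibroblasts (1 and 1 of 8, 0.440). With LPS they were TLR4 (0 and 0 of 12, 0.124), NRF2 (0 and 0 of 16, 0.981), complement (0 and 1 of 17, 0.821), disease-associated microglia (1 and 2 of 19, 0.282), alternatively activated macrophages (1 and 0 of 11, 0.335), pan-reactive (2 and 1 of 12, 0.281), A2 (3 and 0 of 13, 0.0525), cholesterol synthesis (0 and 1 of 24, 0.0777), cell cycle (0 and 0 of 27, 0.454), glycolysis (1 and 1 of 17, 0.812), oxidative phosphorylation (0 and 0 of 27, 0.0793), extracellular matrix (3 and 1 of 26, 0.605), lysosome (0 and 0 of 24, 0.0525), growth factors (1 and 2 of 20, 0.162), immediate early genes (3 and 0 of 18, 0.0658) and markers of astrocytes (0 and 0 of 9, 0.0525), oligodendrocyte lineage (0 and 0 of 10, 0.454), neurons (1 and 0 of 7, 0.497), endothelium (0 and 0 of 6, 0.241) and fibroblasts (0 and 0 of 6, 0.0515). With the replicate number as a block some of these were called: cholesterol synthesis in microglia with ENV (adjusted p = 0.0402, over alternatives from 0.0402 to 0.736), granulocyte markers in microglia with LPS (0.0470, over 0.0182 to 0.337), microglial markers in astrocyte cultures with ENV (0.00718, over 0.00718 to 0.789), and in astrocyte cultures with LPS lysosome (0.0133, over 0.0133 to 0.673) and the markers of astrocytes (0.0133, over 0.0133 to 0.399) and fibroblasts (0.00184, over 0.00184 to 0.399). Lymphocyte markers in every comparison, ependymal markers other than with ENV in astrocyte cultures and granulocyte markers in astrocyte cultures had too few members for the test.

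Fewer genes were called for LPS than for ENV in astrocyte cultures (785 against 2670). This was turned round in replicates 1 and 2 alone (2970 for LPS against 372 for ENV) and small in replicates 3 and 4 alone (892 against 950). With the replicate number as a block the ratio of ENV to LPS calls was 1.67, against 3.40 without it, so differences between replicates 1 and 2 and replicates 3 and 4 may account for part of the gap. Lower depth was argued against, since ENV libraries thinned to the depths of the LPS libraries still gave 2652 calls. A weaker response to LPS stays open: 52.7% of the genes called for both stimuli had an interval for the difference within 2-fold. The share was 62.6% with a replicate block shared by both sets, chosen after seeing the data. Direct edgeR and DESeq2 tests of the difference called 0 genes (76 at an unadjusted p under 0.05 with edgeR).

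Every other split of the libraries into groups of equal size was compared with the real one. For astrocyte ENV, 1 of 35 splits, the real one, gave as many genes (2670, highest other 0). Libraries of equal number correlated, and the 8 splits that part every pair are too few for a share under 0.05. For astrocyte LPS 2 of 35 did (785, highest other 3626), so chance could not be excluded there. The other was replicates 1 and 2 against 3 and 4, which points to a difference between these libraries, and the 7 other splits that parted every pair called 0 genes. Within replicates 1 and 2 the LPS count was 2970 and within 3 and 4 it was 892, and 2611 with the block. In microglia 10 splits were too few for a share under 0.05: ENV had 1 of 10 (3972, highest other 0), LPS 1 of 10 (3647, 0) and the vehicles 10 of 10 (0, 0). The astrocyte vehicles gave 0 genes in the real split, met by 35 of 35, with up to 2830 in the split of replicates 1 and 2 against 3 and 4, and ENV minus LPS gave 0, met by 60 of 60, in microglia (highest other 0) and astrocytes (2927). For lists the numbers were 2 of 10 in microglial ENV (17, highest other 17) and 3 of 10 in microglial LPS (14, 16), too few splits as above. The other splits there called 0 genes but 4 to 17 and 7 to 16 lists, so mislabelled libraries matched the real list counts. In astrocytes the numbers were 14 of 35 for ENV (13, 18) and 21 of 35 for LPS (11, 16). Chance could thus not be excluded for the list counts of either cell type.

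Composition of the microglial libraries is given without a test. Mitochondrially encoded transcripts went from 2.96 ± 0.537 to 1.90 ± 0.360% of counts with ENV and from 2.84 ± 0.118 to 1.45 ± 0.0829% with LPS (SD, n = 3 each), against 2.07 to 2.17% and 1.98 to 2.16% in astrocyte cultures (n = 4 each). Ribosomal protein genes went from 2.41 to 1.54% with ENV and from 1.68 to 0.988% with LPS in microglia, against 1.07 to 1.15% and 1.12 to 1.16% in astrocyte cultures. Summed oligodendrocyte-lineage markers without Cnp stood at 16.8 and 17.1 CPM in microglial H2O replicates 1 and 2 and at 179.5 CPM in replicate 3, which lay near the buffer libraries (304.8 to 339.4 CPM) on PC1. Granulocyte and monocyte markers went from 91.9 ± 25.6 to 295 ± 92.7 CPM with ENV and from 98.4 ± 7.37 to 181 ± 84.6 CPM with LPS, and most of the sum was Csf3r (283.9 and 166.7 CPM in the treated groups). With LPS the rise was in replicates 1 and 2 (229.9 and 230.3 CPM), while LPS replicate 3 stood at 83.5 CPM against 93.7 CPM in H2O replicate 3.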
